A study of Mus musculus with 48 samples.

How the data were processed

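RNA was measured in the tibial metaphysis, the flared bone region below the growth plate, of male mice aged 19 weeks from 8 inbred strains: 129S1/SvImJ, A/J, C57BL/6J, CAST/EiJ, NOD/ShiLtJ, NZO/HlLtJ, PWK/PhJ and WSB/EiJ. The left hindlimb was held in a cast for 3 weeks and the right limb of the same animal served as the contralateral control, per the labels. The labels name 48 libraries in 16 groups of 3, and replicate numbers identify the animal. Tissue was frozen and homogenized, RNA was extracted with a column kit, and stranded poly(A) libraries were sequenced as paired-end reads, per the labels' protocols.

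The deposited table holds whole-number read counts per gene, not normalized, with 1 column per library. The submitters' processing notes name featureCounts, DESeq2 and the mm10 build, with no versions. The aligner, gene annotation, strand setting and filters are not given in the sources used here. The table has 32544 gene rows, of which 7355 have no count in any library. In 27 rows the gene name had been turned into a date, and these were left as they stood. Symbols matched GENCODE M21 (GRCm38) in 31374 rows, and coordinates below come from that annotation. The mm10 sequence derives from C57BL/6J, so reads of the other strains were assigned against a genome not their own.

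Totals ranged from 5253408 to 14744056 counts in 46 libraries, with a median of 7593532. The 2 others were close to empty. A/J control replicate 2 held 2335 counts over 1529 genes, and A/J control replicate 5 held 50 counts over 46 genes. The design fixed before the data were examined named all 48 libraries for every paired comparison. Leaving these 2 libraries out is a departure from that design, and it was decided after both fits had been run and their numbers of called genes had been seen. The grounds do not rest on those numbers. TMM scaling gave the library of 50 counts a factor of 139, so that it entered, on the counts left after the filter, as a library of 6658 counts. Only 17 genes had a count in all 48 libraries, against 13636 in the other 46, so RLE and DESeq2 scaling would rest on those 17. With both libraries kept, the A/J effect of the most abundant genes moved by a median of 0.72 on the log2 scale, and by up to 4.22. The numbers of genes called with all 48 libraries, or all 24 control libraries, stand beside those of the mean effect, of each strain's effect, of the test among strains and of the strain differences in control limbs. They were not computed for each strain's effect against the other 7. Pairs could then be formed in 22 mice (44 libraries), 3 per strain but 1 in A/J, and strain differences in control limbs rest on 22 libraries. The A/J effect therefore has no replicate of its own and is assumed to vary as the other strains do.

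Pairing comes from the series design, in which each mouse gave both limbs. As a check, deviations from the group means correlated between the limbs of a mouse with a median r across genes of 0.09 over 21 mice, from -0.26 to 0.55, and exceeded 0.1 in 10 of them. Between limbs of different mice of a strain the median was -0.04. This second value follows largely from the first, because deviations from a group mean cancel within the group. It gives no separate support for the pairing.

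Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr over the groups, robust quasi-likelihood F test, Benjamini-Hochberg false discovery rate (FDR) of 0.05). The paired model held a term per mouse and a limb term per strain. Its contrasts were the mean of the 8 limb effects, each strain's own effect, and an F test of the differences among the 8 effects. Strain differences were tested with an F test in control and in immobilized limbs separately, followed by each strain against the mean of the other 7. Log2 changes are immobilized minus control, with the standard error (SE), and CPM values were computed by edgeR from the deposited counts, with library sizes scaled by the TMM factors. Adjusted p-values of genes are edgeR's unless another tool is named.

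Gene lists written before the data were examined cover 26 themes: osteoblasts and bone matrix, osteocytes, osteoclasts, osteoclast regulators, Wnt targets, immediate early genes, growth plate chondrocytes, adipocytes, CXCL12-abundant stromal cells, fibrous tissue, skeletal muscle, muscle disuse, erythroid cells, neutrophils, B cells, T and NK cells, macrophages, endothelium, megakaryocytes, cell cycle, oxidative phosphorylation, interferon-stimulated genes, inflammation, circadian clock, glucocorticoid response and hypoxia. They were tested with camera in limma 3.58.1 (preset correlation of 0.01), with camera's estimated correlation and fry beside it. A list score is the mean log2 CPM of its members (prior count of 2). Score differences between limbs were tested 2-sided with 100000 random sign flips over mice, and strain differences with 10000 permutations of strain labels, adjusted over the 26 lists.

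Genes were named by a rule set before the data were examined. For the mean effect it took, among genes past the FDR with a mean CPM of at least 1 and the same direction in at least 18 mice, the 12 largest rises and 12 largest falls. For each strain it took the 4 largest rises and 4 largest falls with the same direction in 3 of 3 mice, which names no A/J gene. It took the 15 smallest p-values of the test among strains, and for each strain the 3 highest and 3 lowest genes in control limbs. Predicted genes were passed over and members of the lists could be named anywhere. The rule had been written for 24 mice. Names outside it were chosen after their values were seen, which is said where they occur.

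The pipeline was tested on simulated counts drawn from the real means and library sizes. With 16791 genes, the mean contrast recovered 68% of genes changed 1.5-fold and 84% changed 2-fold in every strain, with 9 false calls. A change in CAST/EiJ alone was recovered at 58% for 2-fold and 79% for 4-fold in the strain contrast, and at 5% and 53% in the test among strains. The C57BL/6J contrast recovered 6% at 1.5-fold and 40% at 2-fold. For strain differences in control limbs, with 15806 genes, recovery was 18% at 2-fold and 73% at 4-fold. In the list test 0 of 25 unchanged lists were called. These lists held random genes simulated independently of each other. They do not bear on false calls in the real lists, whose members were correlated (estimated correlation 0.563 for osteoblast and 0.919 for erythroid genes).

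Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, a minimum mean CPM of 1, no replicate block, a common limb effect for all strains, a skeletal muscle covariate, each strain's own 6 libraries, and leaving out each mouse in turn. Chosen after seeing the data were marrow covariates (erythroid and neutrophil scores), leaving out A/J mouse 1 and NZO/HlLtJ mouse 4, and the fits on all 48 libraries. Sample identity was checked against strain means: 44 of 46 libraries lay closest to their own strain, and the exceptions, A/J control replicate 1 and NZO/HlLtJ control replicate 4, lay closest to NOD/ShiLtJ. No replicate pair out of 45 held identical counts, and the lowest chi-square per degree of freedom between replicates was 6.36.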

Results

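The data are 48 RNA-seq libraries of the tibial metaphysis of 8 inbred mouse strains, each mouse giving its immobilized left limb and its uncast right limb. Total counts ranged from 5253408 to 14744056 in the 46 usable libraries. The deepest group was NZO/HlLtJ immobilized, at 14024951 ± 673054 counts (SD, n = 3), against 7791314 ± 58622 in the NZO/HlLtJ control limbs. Every cast limb was a left limb, so side and cast cannot be separated in any comparison below. Strain accounted for 61.9% of the variance of log2 CPM, limb for 3.26%, the strain-specific part of the limb effect for 8.79%, and differences between mice of a strain for 15.2%. The residual held 10.9%. Limb had 1 degree of freedom, its strain-specific part 7, and mice and the residual 14 each. Each share includes noise that grows with these, so the shares cannot be compared directly. The first principal component held 21.1% of the variance, and strain explained 92.3% of it.

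The comparison of immobilized with control limbs, averaged over the strains, asks what casting changed irrespective of genetic background. Among genes of the fixed lists, 15 of 21 osteoblast and bone matrix genes and 9 of 16 osteoclast genes rose, and 16 of 20 skeletal muscle genes and 6 of 16 B cell genes fell. As lists, each of the 4 had an adjusted p = 0.168 with an estimated correlation. The type I collagen chain Col1a1 (chromosome 11, 94936224 to 94953042, GRCm38) rose by 1.08 ± 0.23 on the log2 scale (SE, 22 mice, FDR 0.0112), from 9253 to 26570 mean CPM, and was higher in the immobilized limb of 18 of 22 mice. Ctsk, the cathepsin with which osteoclasts degrade collagen (chromosome 3, 95499256 to 95509362), rose by 1.21 ± 0.22 (FDR 0.00639), in 19 of 22 mice. The slow muscle myosin Myh7 (chromosome 14, 54970684 to 54994626) changed by -3.05 ± 0.48 (FDR 0.00305), and was lower in 18 of 22 mice. In all, 1255 of 16882 genes passed the FDR, 773 higher and 482 lower, of which 190 changed by at least 2-fold. With all 48 libraries the count was 1392, with 954 higher and 438 lower. It was 750 with a skeletal muscle covariate, 445 of them shared, and 730 with no filter on low counts. Leaving out A/J replicate 1 gave 2803, NZO/HlLtJ replicate 4 1909, NZO/HlLtJ replicate 6 756 and PWK/PhJ replicate 3 775. Of the 1255 genes, 544 were also called in the same direction in CAST/EiJ, 509 in NOD/ShiLtJ and 94 in the A/J pair. The number was 13 in PWK/PhJ, 1 each in NZO/HlLtJ and WSB/EiJ, and 0 in 129S1/SvImJ and C57BL/6J. Calls within a strain rest on fewer mice.

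Of 21 measured osteoblast and bone matrix genes 15 rose and 0 fell, and 19 rose when adjusted over the list alone. Without PWK/PhJ replicate 3 the number was 9. Besides Col1a1 these included Cthrc1, a secreted protein of collagen-producing cells, at 1.51 ± 0.23, the matrix proteins Ibsp at 1.13 ± 0.26 and Sparc at 1.01 ± 0.19, and Col1a2 at 1.05 ± 0.22. The mean of the list was 0.73 (1.1 without A/J replicate 1), and its score was higher in 17 of 22 mice. By strain the list mean ran from 2.66 in CAST/EiJ to -1.76 in the A/J pair, with 0.308 in C57BL/6J and 0.0686 in WSB/EiJ. Camera gave an adjusted p of 4.77e-15 with the preset correlation and an adjusted p = 0.168 with an estimated correlation. The sign-flip permutation test of the score gave p = 0.0335, or 0.124 after adjustment over the 26 lists. Of the members not called, Runx2, a transcription factor of the osteoblast lineage, had 0.15 ± 0.10, and Bglap, encoding osteocalcin, 0.77 ± 0.23 (FDR 0.0517). In the same limbs the muscle score was lower by 1.93, averaged over strains. None of the 11 osteocyte genes passed the FDR, the list mean being 0.18 (adjusted p = 0.691 with an estimated correlation), and Sost, the osteocyte inhibitor of Wnt signalling, had 0.17 ± 0.29.

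Osteoclast genes rose in 9 of 16 cases, or 13 adjusted over the list alone, and 0 fell. Acp5, encoding tartrate-resistant acid phosphatase, rose by 0.78 ± 0.18, the gelatinase Mmp9 by 0.66 ± 0.12, and the fusion factors Dcstamp and Ocstamp by 0.90 ± 0.18 and 0.93 ± 0.15. The score was higher in 18 of 22 mice (permutation p = 0.00014, adjusted 0.00325), and camera gave an adjusted p of 9.73e-09, or adjusted p = 0.168 with an estimated correlation. The list mean was highest in NOD/ShiLtJ (1.2), and it was 0.0549 in PWK/PhJ and -0.0391 in WSB/EiJ. Among the 10 osteoclast regulators 0 passed the FDR (list mean 0.15, adjusted p = 0.699 with an estimated correlation). Tnfsf11, encoding RANKL, had 0.33 ± 0.16 and its decoy receptor Tnfrsf11b had 0.00 ± 0.27.

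Growth plate genes had a list mean of 1.29, the score being higher in 16 of 22 mice (permutation p = 0.00323, adjusted 0.021). Only Col11a1 (1.06 ± 0.27) and Col11a2 (0.70 ± 0.20), of 19 members, passed the FDR over all genes (Col11a2 lost its call in 16 of 22 fits that left out a mouse, the highest FDR being 0.0813 without WSB/EiJ replicate 5), and 10 passed adjusted over the list alone. Camera's adjusted p was 8.32e-07, and adjusted p = 0.366 with an estimated correlation. The type X collagen Col10a1 had 3.26 ± 1.06 (FDR 0.0705). In the fibrous tissue list 3 of 15 rose, Col3a1 (0.99 ± 0.29), Dcn (0.67 ± 0.17) and Lum (1.10 ± 0.23), with a list mean of 0.42 (0.671 without A/J replicate 1 and 0.802 with a skeletal muscle covariate), an adjusted p of 0.00146, or 0.131 with fry, and adjusted p = 0.629 with an estimated correlation. Col3a1 lost its call in 16 of 22 such fits, the highest FDR being 0.078 without PWK/PhJ replicate 3.

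Of 20 skeletal muscle genes 16 fell, all 20 when adjusted over the list alone, with a list mean of -2. The number was 4 without NZO/HlLtJ replicate 6, PWK/PhJ replicate 3, WSB/EiJ replicate 5 or 129S1/SvImJ replicate 3 or 6. Among them the fast myosin Myh2 changed by -2.91 ± 0.59 and the skeletal actin Acta1 by -2.27 ± 0.64 (call lost in 11 of 22 fits that left out a mouse, the highest FDR being 0.0836 without NZO/HlLtJ replicate 6). With a skeletal muscle covariate, which removes muscle content, Acta1 turned to 0.0856. The score was lower in 15 of 22 mice (permutation p = 0.00323, adjusted 0.021), with a camera adjusted p of 2.24e-17 and adjusted p = 0.168 with an estimated correlation. The fall was not shared by all mice: the score rose by 3.76 in C57BL/6J mouse 4 and by 1.36 in CAST/EiJ mouse 4. Of the 14 genes known to be induced in disused muscle, Fbxo32 (-0.57 ± 0.15) and Trim63 (-1.49 ± 0.44), ubiquitin ligases of muscle atrophy, and the developmental myosin Myh8 (-1.51 ± 0.44) fell, while the cell cycle inhibitor Cdkn1a rose by 0.55 ± 0.13. That list had a mean of -0.70, an adjusted p of 0.0294 and adjusted p = 0.669 with an estimated correlation. The call was lost with all 48 libraries (adjusted p of 0.0809), with marrow covariates (0.0693), with fry (0.246) and without A/J mouse 1 and NZO/HlLtJ mouse 4 (mean of -0.31, 0.71). With the muscle covariate the list turned to 0.324 (adjusted p of 0.38) and Trim63 to 0.146. The call of the list was also lost without A/J replicate 1 (adjusted p of 0.288), C57BL/6J replicate 1 (0.0584), NZO/HlLtJ replicate 4 (0.0874) or PWK/PhJ replicate 6 (0.0687). Without A/J replicate 1 the FDR was 0.133 for Fbxo32 and 0.105 for Trim63, and without C57BL/6J replicate 4 it was 0.111 for Myh8.

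B cell genes fell in 6 of 16 cases, 14 adjusted over the list alone, and the score was lower in 17 of 22 mice (permutation p = 0.00765, adjusted 0.0398). The recombinase Rag1 changed by -0.98 ± 0.20, and the lineage factors Pax5 and Ebf1 by -0.69 ± 0.17 and -0.39 ± 0.08. The list mean was -0.55, with an adjusted p of 4.94e-09 and adjusted p = 0.168 with an estimated correlation. Ebf1 lost its call without A/J replicate 1 (FDR 0.104). Interferon-stimulated genes were lower by 0.22 in the score averaged over strains, in 18 of 22 mice (permutation p = 0.00025, adjusted 0.00325). Here 5 of 17 fell, 6 adjusted over the list alone, among them Oas2 (-0.66 ± 0.18), Usp18 (-0.47 ± 0.12), Mx1 (-0.44 ± 0.11) and Isg15 (-0.41 ± 0.11). The number was 3 without CAST/EiJ replicate 3, WSB/EiJ replicate 2 or 129S1/SvImJ replicate 6. Oas2 lost its call in 3 fits that left out a mouse (FDR 0.096 without CAST/EiJ replicate 3) and Isg15 in 7 (0.0582 without PWK/PhJ replicate 3). Camera gave an adjusted p of 0.000379, and adjusted p = 0.168 with an estimated correlation. The oxidative phosphorylation list was called by camera (adjusted p of 0.00791) with a mean of -0.08 and 0 of 21 members past the FDR, and adjusted p = 0.699 with an estimated correlation. The call was lost with all 48 libraries (adjusted p of 0.187), with marrow covariates (0.0901) and with fry (0.391). The mean turned to 0.128 with the muscle covariate (adjusted p of 0.0149), and was -0.129 without A/J replicate 1 and -0.0548 without 129S1/SvImJ replicate 3.

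The remaining lists were not called. Single members that passed the FDR were the Wnt target Notum (0.63 ± 0.16), the immediate early genes Jund (0.34 ± 0.08) and Klf4 (0.40 ± 0.10), the stromal genes Pdgfra (0.50 ± 0.12) and Ebf3 (-0.31 ± 0.07), the macrophage gene Vsig4 (0.78 ± 0.19), the inflammatory genes Ccl7 (1.56 ± 0.39) and Nfkbia (0.22 ± 0.06), the glucocorticoid-responsive genes Tsc22d3 (-0.37 ± 0.09) and Zbtb16 (-0.43 ± 0.12), and the glycolytic gene Aldoa of the hypoxia list (-0.69 ± 0.18). Without A/J replicate 1 the FDR was 0.225 for Ebf3 and 0.0811 for Zbtb16, without PWK/PhJ replicate 3 it was 0.122 for Ccl7, and without NZO/HlLtJ replicate 6 it was 0.0524 for Aldoa. List means were 0.14 for Wnt targets (adjusted p 0.201), 0.22 for immediate early genes (0.0711), 0.03 for stromal cells (0.813), 0.11 for macrophages (0.209), 0.15 for inflammation (0.279), -0.10 for the glucocorticoid response (0.209) and -0.05 for hypoxia (0.387). No member passed in the lists of adipocytes (mean -0.18, adjusted p 0.055), erythroid cells (-0.09, 0.716), neutrophils (0.18, 0.0711), T and NK cells (-0.18, 0.0506), endothelium (-0.06, 0.254), megakaryocytes (-0.14, 0.242), cell cycle (-0.06, 0.259) and circadian clock (-0.04, 0.408).

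Outside the lists, the largest rises taken by the rule included Bcan, encoding the proteoglycan brevican (chromosome 3, 87987531 to 88000230), at 2.34 ± 0.26 (FDR 0.000223, 18 of 22 mice). They also included the secreted factor C1qtnf3 (2.06 ± 0.51), the channel protein Panx3, found in osteoblasts and chondrocytes (1.88 ± 0.38), the neuropeptide Gal (1.76 ± 0.27, higher in 21 of 22 mice), Rarres1 (1.71 ± 0.37), the carbonic anhydrase Car12 (1.70 ± 0.40), the retinoic acid binding protein Crabp2 (1.69 ± 0.38) and Arfgef3 (1.51 ± 0.37). Stfa2 (1.97 ± 0.27), Stfa3 (2.19 ± 0.39) and BC100530 (2.36 ± 0.48) belong to the stefin A family of close copies on chromosome 16, so the assignment of reads among them is uncertain. The largest falls, Tnni1 (-3.18 ± 0.56), Ckmt2 (-2.91 ± 0.62), Myl2 (-2.87 ± 0.44), Smtnl1 (-2.78 ± 0.61), Apobec2 (-2.49 ± 0.57), Myoz2 (-2.20 ± 0.46), Scn4b (-1.89 ± 0.43), Cox8b (-1.82 ± 0.47), Smtnl2 (-1.75 ± 0.35), Itgb1bp2 (-1.71 ± 0.43) and Csrp3 (-1.70 ± 0.47), are with Myh7 mostly genes of striated muscle. Of these 24 genes 20 passed the FDR in all 22 fits that left out a mouse. Csrp3 lost its call in 13 of them (highest FDR 0.0642, without C57BL/6J replicate 1), Cox8b in 4 (0.0613, without NZO/HlLtJ replicate 6), Ccl7 in 2 and BC100530 in 1 (0.235, without PWK/PhJ replicate 4).

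**Figure D1:**
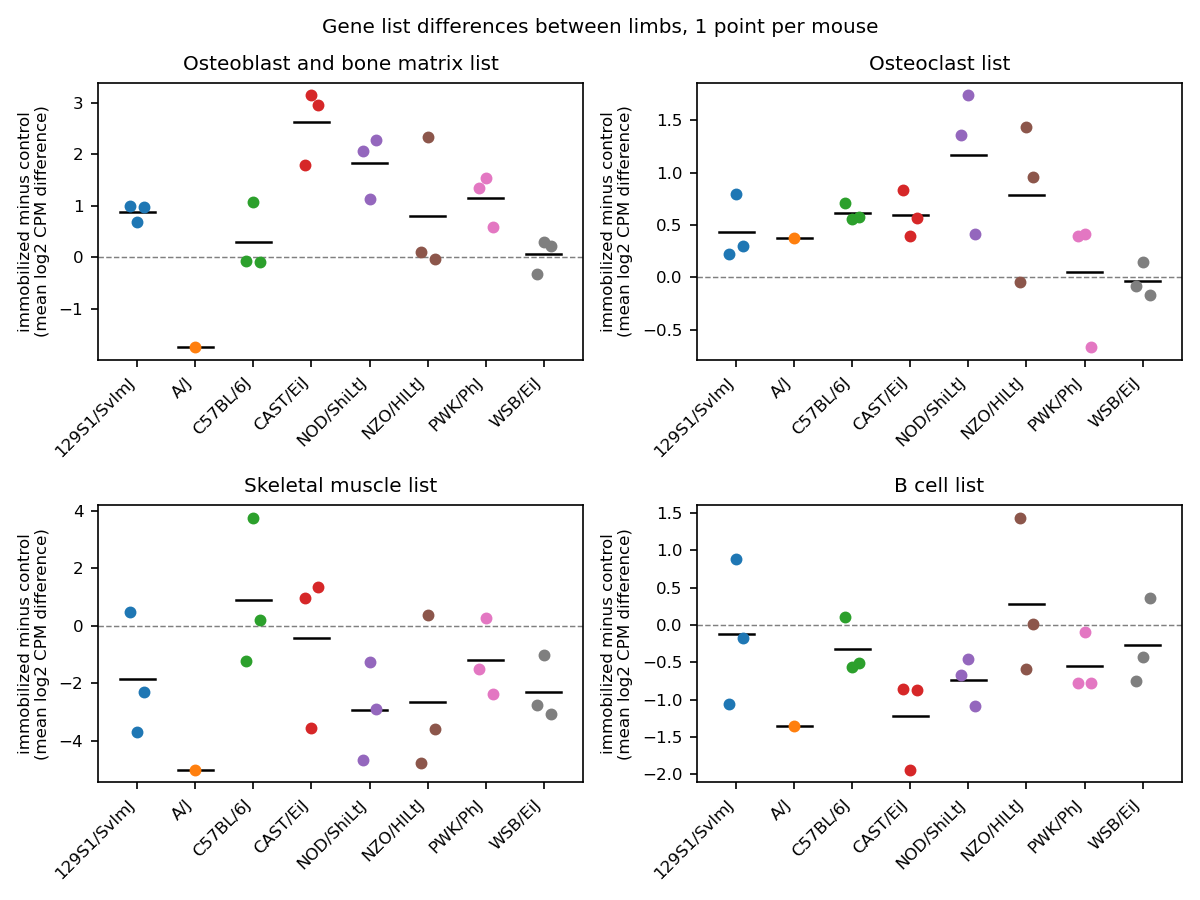
Difference of 4 gene list scores between the immobilized and the control limb (vertical axis, mean log2 CPM difference) for each of 22 mice, by strain. Each point is a mouse and each black line the mean of its strain. The osteoblast score is highest in CAST/EiJ, at 1.79 to 3.15 in its 3 mice, and is -1.75 in the single A/J pair.

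Effects within each strain ask how far the response depended on genetic background. They were largest in number in CAST/EiJ, where 2339 genes passed the FDR, 1415 higher and 924 lower (2217 with all 48 libraries). Of 21 osteoblast genes 19 rose, with a list mean of 2.66 (adjusted p = 0.0237 with an estimated correlation), and Col1a1 rose by 3.79 ± 0.62, from 4286 ± 1530 to 60630 ± 25700 CPM (SD, n = 3). Wnt targets rose in 5 of 11 cases with a mean of 1.22 (adjusted p = 0.0237 with an estimated correlation), among them Tcf7 by 1.93 ± 0.33, Nkd2 by 1.90 ± 0.35 and Notum by 1.63 ± 0.34. Adipocyte genes rose in 6 of 17 cases (mean 1.26, adjusted p = 0.37 with an estimated correlation). B cell genes fell in 6 of 16 cases (mean -1.22, adjusted p = 0.104 with an estimated correlation), and megakaryocyte genes in 4 of 10 (mean -1.30, adjusted p = 0.37 with an estimated correlation). The genes taken by the rule were Nell1, encoding a secreted protein that promotes bone formation (5.94 ± 0.79, from 0.313 to 19.3 CPM), Bcan (5.29 ± 0.68), Fstl4 (4.47 ± 1.06), Fetub (4.40 ± 0.80), Rag1 (-3.06 ± 0.47), the interleukin 7 receptor Il7r (-2.85 ± 0.37) and Robo3 (-2.80 ± 0.73). The rule also took Rps12l1, a processed pseudogene that shares reads with its parent gene and is uncertain. Without the replicate block 1259 genes passed. Leaving out CAST/EiJ replicate 2, 3 or 4 gave 1016, 821 or 679 genes, and Fstl4 and Robo3 were no longer called without replicate 3 or 4.

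In NOD/ShiLtJ 1407 genes passed, 937 higher and 470 lower (1455 with all 48 libraries). Osteoblast genes rose in 16 of 21 cases (mean 1.83, adjusted p = 0.157 with an estimated correlation), osteoclast genes in 8 of 16 (mean 1.2, adjusted p = 0.172 with an estimated correlation) and Wnt targets in 5 of 11 (mean 0.78, adjusted p = 0.157 with an estimated correlation). Ctsk rose by 2.62 ± 0.58, Acp5 by 1.69 ± 0.48 and Col1a1 by 2.26 ± 0.59. The genes taken by the rule were Tcfl5 (5.61 ± 1.36), Jakmip3 (5.45 ± 1.42), Car12 (4.46 ± 1.02), Nell1 (4.06 ± 0.93), Fbp2 (-5.56 ± 1.46), Ckmt2 (-4.72 ± 1.31), Mettl21e (-4.72 ± 1.26) and the guanylate binding protein Gbp10 (-4.47 ± 0.92), whose family shares sequence and which is uncertain. Muscle genes had a mean of -2.94 in the same limbs, with 1 of 20 past the FDR, and 15 of 21 oxidative phosphorylation genes fell (mean -0.752, adjusted p = 0.255 with an estimated correlation). The count rested on single mice: it was 0 without NOD/ShiLtJ replicate 4 (none of these 8 genes was then called) and 2 without replicate 6, and 397 in the strain's own 6 libraries.

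In PWK/PhJ 15 genes passed, 6 higher and 9 lower (13 with all 48 libraries), of 2066 at an unadjusted p under 0.05. H1f0, a linker histone, rose by 1.15 ± 0.15, Rab11fip4 by 1.2 ± 0.17, C1qtnf6 by 1.88 ± 0.35 and Gpx7 by 2.21 ± 0.38. The interferon-stimulated genes Oas2 (-1.98 ± 0.36) and Isg15 (-1.40 ± 0.26) fell, as did Ppid (-0.92 ± 0.11) and Spg11 (-0.91 ± 0.15). DESeq2 called 152 genes, and the count was 0 without PWK/PhJ replicate 4 and 212 without replicate 6. None of these 8 genes was called without replicate 4, and without replicate 3 the FDR of Gpx7, C1qtnf6, Oas2 and Spg11 was 0.712 and that of Isg15 0.75. In WSB/EiJ the 1 gene past the FDR was Adra2a, an adrenergic receptor, which rose by 1.79 ± 0.26 (FDR 0.0293), from 4.51 ± 1.99 to 15.2 ± 4.7 CPM (SD, n = 3). All 48 libraries also gave 1, and DESeq2 called 21. Adra2a lost its call in 8 of 22 fits that left out a mouse, with a highest FDR of 0.267 without WSB/EiJ replicate 4. In C57BL/6J and NZO/HlLtJ the only gene past the FDR was a predicted one, Gm28438 and Gm4070, named after their values were seen (2 and 1 genes with all 48 libraries). DESeq2 called 5 and 18, and in C57BL/6J the strain's own 6 libraries gave 142. The count was 0 without C57BL/6J replicate 1 or 4, and 0 in NZO/HlLtJ without its replicate 6. In 129S1/SvImJ edgeR called 0 genes, with 767 at an unadjusted p under 0.05, where DESeq2 called 5, limma-voom 0 and edgeR with all 48 libraries 0. NZO/HlLtJ growth plate genes had a mean of 3.90 (adjusted p = 0.0106 with an estimated correlation), with 0 of 19 members past the FDR. In the same strain muscle disuse genes had a mean of -3.47 (adjusted p = 0.0106 with an estimated correlation) and inflammation genes -1.04 (adjusted p = 0.0239 with an estimated correlation), also with 0 members past the FDR. Both rested on NZO/HlLtJ mouse 4: the muscle disuse score differed by -3.65 in it and by -0.295 and -0.922 in mice 5 and 6, and the inflammation score by -2.29 against 0.205 and 0.214. Skeletal muscle genes had -2.88 and erythroid genes 1.05 (adjusted p = 0.0861 and 0.085 with an estimated correlation), and the erythroid score of NZO/HlLtJ control replicate 4 was 2.96, against 9.41 and 9.77 in the other control limbs.

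The A/J effect rests on 1 pair, in which 674 genes passed, 458 higher and 216 lower (927 with all 48 libraries), on the assumption that this pair varied as those of other strains did. It was 13 without the replicate block, 15 with a muscle covariate and 1769 with DESeq2. In this pair the osteoblast list had a mean of -1.76, skeletal muscle -5.04 and neutrophils 2.32, with adjusted p = 0.288 for each with an estimated correlation. The fit without the replicate block also held A/J immobilized replicates 2 and 5, which have no usable partner, so its count differs by samples as well as by pairing. The control limb of the pair had an osteoblast score of 9.14, above every other strain's mean in control limbs.

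**Figure D2:**
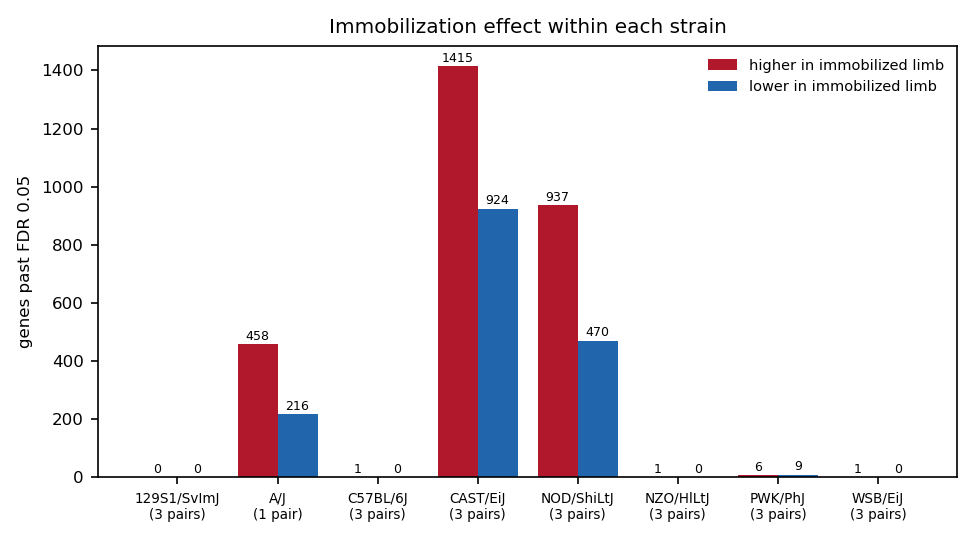
Number of genes past an FDR of 0.05 within each strain (vertical axis), in red for higher and in blue for lower expression in the immobilized limb, with the number of mouse pairs under each strain. CAST/EiJ has 1415 higher and 924 lower genes and NOD/ShiLtJ 937 and 470, while 129S1/SvImJ has 0.

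Whether the limb effect differed among strains was tested directly, and 422 of 16882 genes passed the FDR (484 with all 48 libraries). Bgn, encoding biglycan, differed from 1.93 in CAST/EiJ to -2.29 in A/J, the procollagen protease Adamts2 from 2.30 to -1.87, the proprotein convertase Pcsk5 from 2.36 to -3.24, C1qtnf6 from 3.59 to -2.12, C1qtnf1 from 1.57 to -1.48, and the Wnt co-receptor Lrp5 from 1.25 to -1.84, each with FDR 0.0102. The other genes taken by the rule were Cd1d1, Mxd4, Btla, Evl, Rab11fip4, Metrnl, Ctsf, Pid1 and Bcl7a, all with the same FDR, and Bcl7a alone had a negative value in CAST/EiJ (-1.36). A score difference among strains was found by permutation for Wnt targets (adjusted p 0.0052) and osteoblast genes (adjusted p 0.0208), and for neither without A/J (adjusted p 0.13 for both). The test rested on the A/J pair: without it 4 genes passed, of which Bcl7a (FDR 0.0361) was the only one of the 15 named. Bcl7a itself was lost without CAST/EiJ replicate 3 (FDR 0.058), and 31 genes passed in that fit. The test gave 17 genes with marrow covariates and 2157 with DESeq2.

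Against the mean of the other 7 strains, the effect differed for 1341 genes in CAST/EiJ, 1584 in A/J, 29 in NOD/ShiLtJ, and 1 each in C57BL/6J and NZO/HlLtJ. CAST/EiJ differed in Nell1 (by 4.51, FDR 0.0153), Bcan (3.37, FDR 0.0186), Col1a1 (3.11, FDR 0.0102) and Tcf7 (1.76, FDR 0.00935). In 129S1/SvImJ, PWK/PhJ and WSB/EiJ edgeR found 0 genes, with 223, 1251 and 1046 at an unadjusted p under 0.05, and no other tool was run on this contrast. CAST/EiJ and NOD/ShiLtJ shared 511 rising genes, where independent lists would share 78.5, and 37 falling genes, where they would share 25.7. For 8 genes they went opposite ways, and the correlation of their effects across genes was 0.388. CAST/EiJ and A/J called 161 genes in opposite directions, with a correlation across genes of -0.283, while that of A/J with NZO/HlLtJ was 0.308 and with WSB/EiJ 0.252. Genes are not independent replicates in these correlations.

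Strain differences in control limbs compare genetic backgrounds in the uncast limb of mice whose other limb was cast. Limbs of mice without any cast were not measured. Tissue content and the assignment of reads against mm10 can contribute to such differences. Control limbs differed among strains in 6704 of 16493 genes (6311 with all 24 control libraries), and in 4147 with a muscle covariate. In immobilized limbs strain differences were found in 7785 of 15478 genes. Of 15439 genes tested in both, 4525 were called in both, where independent lists would share 3156. Both limbs came from the same mice and were assigned against the same genome, so the lists are not independent. The shared calls are not a replication. Against the other 7 strains the count was 3743 in CAST/EiJ, 2750 in PWK/PhJ, 1784 in NOD/ShiLtJ, 1457 in C57BL/6J, 1078 in WSB/EiJ, 1071 in 129S1/SvImJ, 760 in NZO/HlLtJ and 279 in A/J, where 1 control library remained. CAST/EiJ and PWK/PhJ derive from other subspecies than most laboratory strains. Genes called lower made up from 15.4% of calls in NOD/ShiLtJ to 42.2% in CAST/EiJ, and 34% in C57BL/6J, whose genome is the reference.

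Several immune genes differed by orders of magnitude. Chil3, a chitinase-like protein of myeloid cells, stood at 0.744 ± 0.757 CPM in NZO/HlLtJ and 0.4 ± 0.183 in PWK/PhJ, against 2429 ± 438 in C57BL/6J and 2730 ± 426 in CAST/EiJ (SD, n = 3, F test FDR 2.21e-08). Ifi202b, an interferon-inducible gene, had no count in the 3 C57BL/6J control libraries and 87.7 ± 36 CPM in NZO/HlLtJ (FDR 1.46e-09). Tgtp2, a T cell GTPase of a multicopy family, and Wfdc17 had no count in CAST/EiJ, against 19.3 ± 3.58 and 54.6 ± 12.6 CPM in C57BL/6J. The potassium channel subunit Kcnmb3 stood at 12.5 ± 1.72 CPM in CAST/EiJ and at or below 0.104 in the mean of every other strain. Eno1b, a retrogene copy of enolase with 0.292 ± 0.506 CPM in C57BL/6J and 444 ± 54.3 in CAST/EiJ, shares reads with Eno1 and is uncertain, as are the other genes of the rule that are retrogenes, pseudogenes or immunoglobulin segments. Zero counts in a strain cover counting error only. In strains other than C57BL/6J, the strain of the reference, they cannot be separated from sequence differences against it.

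Of the 26 list scores, 7 differed among strains in control limbs by permutation. Interferon-stimulated genes were highest in C57BL/6J (mean log2 CPM of 4.38) and lowest in CAST/EiJ (2.31), with 16 of 17 members differing (adjusted p 0.0013). Macrophage genes ranged from 5.65 in NOD/ShiLtJ to 6.26 in PWK/PhJ (adjusted p 0.0013), and glucocorticoid-responsive genes from 4.78 in PWK/PhJ to 6.02 in 129S1/SvImJ (adjusted p 0.00173). Skeletal muscle genes ranged from 4.26 ± 0.639 in WSB/EiJ to 10 ± 1.08 in NOD/ShiLtJ (SD, n = 3, permutation adjusted p 0.0124). The hypoxia list (adjusted p 0.013) and the osteocyte and stromal lists (adjusted p 0.0308 for both) also differed. In NZO/HlLtJ control replicate 4 the erythroid score was 2.96 and the neutrophil score 6.17, while in the other NZO/HlLtJ control libraries the erythroid score was 9.41 and 9.77 and the neutrophil score 9.87 in each.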

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

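The tests on the osteoblast genes and on the A/J pair, the marrow covariates and the fits without A/J mouse 1 and NZO/HlLtJ mouse 4 were chosen only after the results were seen, and the tests on the A/J pair were changed after their first values were known.

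In the direct test of differences among strains in the effect of the cast 422 genes differed, and 4 without the single A/J pair, while against the mean of the other 7 strains 1584 genes differed in A/J, 1341 in CAST/EiJ, 29 in NOD/ShiLtJ, 1 in C57BL/6J and 1 in NZO/HlLtJ, with no fit of these without A/J. C1qtnf1, Adamts2, Cd1d1, Mxd4, Btla, Evl, Bgn, Pcsk5, C1qtnf6, Lrp5, Rab11fip4, Metrnl, Ctsf, Bcl7a and Pid1 each had an interaction FDR of 0.0102, and only Bcl7a passed without A/J. List scores differed among strains for osteoblast genes (adjusted p 0.0208) and Wnt targets (adjusted p 0.0052), and for neither without A/J.

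The first pattern is the rise of osteoblast genes in immobilized limbs. At an equal muscle score in both limbs, regression over 22 mice left an osteoblast difference of 1.24 (SE 0.302; r = 0.322, permutation p 0.145). With a muscle covariate 13 of 21 genes still rose (mean 0.995), so adjusting for the muscle score did not remove the rise. The regression weights mice equally and treats them as independent, while the osteoblast score differed among strains, so its SE may be too small. It cannot decide how much less attached muscle accounts for. A larger share of bone against marrow was tested in the same way and left 0.856 (SE 0.224), with 9 genes risen under marrow covariates (mean 0.782). This cannot decide how much that share accounts for, because bone can gain share while log2 marrow scores fall little. The share may account for part of the pattern or more, since the osteoblast difference fell as marrow genes rose (r = -0.509, permutation p 0.0167, adjusted over 4 relations 0.0668; rho = -0.66, permutation p 0.00104; r = -0.716 without the 2 mice farthest from the median). Left and right tibiae cannot be told apart from cast and uncast, because 0 cast limbs were right limbs.

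The second pattern is the A/J pair, in which most genes called in the mean of the other strains had the opposite sign, although its effects correlated across genes with those of NZO/HlLtJ at 0.308 and CAST/EiJ at -0.283. Among 2803 genes called without A/J, 77.1% of the rising genes were lower and 60.5% of the falling genes were higher in this pair. Exchanged limbs cannot be told apart from an effect of strain by the lower of these shares: each of the other 21 pairs, on the genes called without it, would give from 15% to 92.5% if exchanged, and as labelled they gave up to 68.8%, in NZO/HlLtJ mouse 4. That mouse also gave the 15%. Apart from that mouse, shares were at least 36.4% if exchanged (129S1/SvImJ mouse 2) and at most 42.7% as labelled (PWK/PhJ mouse 6). The immobilized library of the A/J pair had osteoblast and muscle scores of 7.38 and 4.47. A/J immobilized replicates 2 and 5 had 7.52 and 4.17, and 6.36 and 6.63, against 9.14 and 9.47 in control replicate 1. With 1 control library these scores do not decide on an exchange. The osteoblast list mean of -1.76 became -1.08 with a muscle covariate and -1.2 with marrow covariates, where mice of a strain vary with an SD of 0.711. The muscle and the marrow content of this pair likewise cannot be told apart from an effect of strain, as 1 pair remained.

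In NZO/HlLtJ mouse 4, 85% of rising and 68.8% of falling genes called without it had the opposite sign, and exchanged limbs were not excluded there either. Its control library had an erythroid score of 2.96, against 8.7 in its immobilized limb and 9.41 and 9.77 in the other NZO/HlLtJ control limbs. The mean difference of the erythroid, neutrophil, B cell and megakaryocyte scores was 3.22 in this mouse, and the osteoblast difference 0.0936. Tissue content of this 1 control library is another explanation, which was not tested. Either explanation bears on the NZO/HlLtJ effect and on the mean effect, which had 1909 genes without that mouse and 3907 without both mice.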

How the results depend on the processing

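The fits on all 48 libraries, the marrow covariates and the fits without A/J mouse 1 and NZO/HlLtJ mouse 4 were chosen after seeing the data. The first of these is the design as fixed beforehand, from which the reported fits depart. The cause of the changes below was not tested. RLE scaling kept the counts within 1.5 times, as did a minimum CPM of 1. The split of the mean effect into 773 higher and 482 lower genes became 545 and 514 without the replicate block, 694 and 523 with RLE, and 767 and 570 with a minimum CPM of 1. Depth limits genes of low count in particular, and the 2 near-empty libraries leave A/J with 1 pair.

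The mean effect (1255 genes) gave 730 with no filter, 750 with a muscle covariate and 3907 without the 2 mice, 1045 of them shared. With DESeq2 the counts were 5 in 129S1/SvImJ, 1769 in A/J, 5 in C57BL/6J, 18 in NZO/HlLtJ, 152 in PWK/PhJ, 21 in WSB/EiJ and 2157 in the test among strains. With limma-voom they were 8 in NZO/HlLtJ, 28 in PWK/PhJ and 4 in WSB/EiJ. Without the replicate block, which ignores the pairing, they were 13 in A/J, 2 in C57BL/6J, 1259 in CAST/EiJ, 0 in WSB/EiJ (edgeR) and 174 among strains. The muscle covariate gave 15 in A/J, 49 in PWK/PhJ, 2 in WSB/EiJ, 226 among strains and 4147 for control limbs. Marrow covariates gave 5 in 129S1/SvImJ, 0 in A/J, 5 in PWK/PhJ and 17 among strains. With no filter A/J had 302. A strain's own 6 libraries gave 142 in C57BL/6J, 397 in NOD/ShiLtJ, 0 in NZO/HlLtJ, 9 in PWK/PhJ and 0 in WSB/EiJ, and A/J could not be fitted so. Without the 2 mice the counts were 2 in C57BL/6J, 29 in PWK/PhJ, 2 in WSB/EiJ and 13 among strains. All 48 libraries gave 2 in C57BL/6J. Of 26 lists 9 were called, 0 with an estimated correlation, 14 with no filter, 14 with the muscle covariate and 19 without the 2 mice. The fit without the block held all 46 usable libraries, with A/J immobilized replicates 2 and 5 added, so its changes do not come from the pairing alone. No other count moved by over 1.5 times without the block, and single genes lost there were 24 of 93 for the mean effect, 5 of 25 within strains and 2 of 15 among strains.

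Leaving out each mouse gave 756 to 2803 genes for the mean effect, 0 to 2 in 129S1/SvImJ, 386 to 1142 in A/J, 0 to 2 in C57BL/6J, 679 to 2844 in CAST/EiJ, 0 to 1787 in NOD/ShiLtJ, 0 to 3 in NZO/HlLtJ, 0 to 212 in PWK/PhJ, 0 to 2 in WSB/EiJ, and 4 (without A/J replicate 1) to 1185 (without NZO/HlLtJ replicate 5) among strains, where 18 of 22 fits moved by over 1.5 times. It gave 5103 to 9107 for control limbs, 6932 to 8548 for immobilized limbs and 8 to 14 lists.

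Reversed values occurred only under the muscle covariate, which removes muscle content by construction. The muscle disuse list turned to 0.324 and oxidative phosphorylation to 0.128, and the genes were Cox8b (0.16), Acta1 (0.0856), Myh4 (0.205), Tnnt3 (0.215), Tnni2 (0.254), Tnnc2 (0.252), Actn3 (0.28), Pvalb (0.18), Atp2a1 (0.0841), Mybpc2 (0.048), Eno3 (0.00959) and Trim63 (0.146). Of the 15 genes named among strains 14 lost their call with marrow covariates and 13 without the 2 mice. Of 93 genes of the mean effect 47 lost it with marrow covariates, 41 with the muscle covariate and 35 with no filter, in the same direction.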

Other observations

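The list of secretory pathway genes and the list of heat shock chaperones were written after other genes of each kind had been seen, and leave those out. The tests on the chaperones and the other splits were stated before their results.

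Of 30 measured genes that act on collagen or in the secretory pathway, 21 rose in immobilized limbs and 0 fell, with a mean of 0.391, and the score was higher in 18 of 22 mice (permutation p 0.00559, camera p = 0.0367 with an estimated correlation). Lox, the enzyme that crosslinks collagen, rose by 1.15 ± 0.23 (SE), the retrieval receptor Kdelr3 by 1.02 ± 0.18, the collagen chaperone Fkbp10 by 0.95 ± 0.16 and the transcription factor Creb3l1 by 0.82 ± 0.16. Members not called include the chaperones Hspa5 (0.03 ± 0.06) and Calr (0.03 ± 0.06), while the disulfide isomerase P4hb rose by 0.32 ± 0.07. By strain the list mean was 1.10 in CAST/EiJ and 1.05 in NOD/ShiLtJ, higher in 3 of 3 mice of each, and -0.475 in the A/J pair. The osteoblast list moved with it, at 2.66, 1.83 and -1.76 in these strains, and the muscle score was lower by 1.93 averaged over strains. Tissue composition was not tested for this list.

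Heat shock chaperones may be lower in immobilized limbs. The 18 measured genes had a mean of -0.152 and a median of -0.0756, the score was lower in 18 of 22 mice, and the sign-flip permutation p was 0.00024. The list left out the genes already seen, but its members were measured in the same mice. This p therefore does not exclude chance from picking the theme. No gene passed the FDR in edgeR, and the p was 0.133 with an estimated correlation. The largest falls were in Hspb1 (-0.763 ± 0.25, higher in 10 of 22 mice) and Hspa1a (-0.663 ± 0.342, higher in 5). The difference was -0.114 (SE 0.0421) at an equal muscle score and -0.128 (SE 0.046) at an equal osteoblast score. Neither score was clearly related to it (r = 0.341 and -0.199, permutation p 0.122 and 0.376). These regressions therefore cannot decide how much tissue content accounts for. Limb temperature under the cast and the order of dissection are untested here, and the pattern remains a hypothesis.

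Other splits of the samples were fitted with limma-voom. For the mean limb effect 4 of 100 exchanges of the limbs within mice, the real arrangement included, gave at least its 1088 genes. That share lies under the 0.05 set beforehand, but narrowly for 100 splits, so chance is not firmly excluded. The other splits that reached the real count gave 3059, 2934 and 1916 genes, more than the real labels. All kept the 3 CAST/EiJ mice on one side, as did other splits that gave 0 genes. In those of 3059 and 2934 genes the A/J pair was exchanged relative to the CAST/EiJ mice. This points to a structure of the samples that was not resolved. Chance can be excluded for the strain differences in control limbs (1 of 100 splits, 6052 genes, highest other 214). The same holds in immobilized limbs (1 of 100, 7381 genes, highest other 20). For differences among strains in the limb effect 1 of 100 splits was as large (519 genes, highest other 358). There the A/J pair alone makes up its strain, while most permutations of strain labels place it with other mice. In edgeR 4 genes passed without that pair, and the count also fell without CAST/EiJ replicate 3. These splits therefore do not separate a difference among strains from what sets 1 pair apart. Within a strain there are 4 splits, too few for a share under 0.05. The real and the highest other counts were 0 and 1 in 129S1/SvImJ (4 of 4 as large), 1 and 0 in C57BL/6J (1 of 4), 2490 and 0 in CAST/EiJ (1 of 4), 1866 and 0 in NOD/ShiLtJ (1 of 4), 8 and 16 in NZO/HlLtJ (3 of 4), 28 and 21 in PWK/PhJ (1 of 4) and 4 and 2 in WSB/EiJ (1 of 4).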
